A study of Mus musculus with 8 samples.

How the data were processed

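RNA from the cerebral cortex of 8 mouse embryos was sequenced, 4 in which Taf8 was deleted and 4 with intact Taf8. Per the labels, each library came from a separate embryo, RNA was isolated with a Qiagen RNeasy kit, and polyadenylated RNA was made into unstranded TruSeq libraries that were read as paired ends on an Illumina HiSeq instrument. The intact embryos are described as homozygous wild type and the deleted embryos as carrying a null allele and a loxP-flanked allele. The embryonic stage and the recombinase are not given in the sources used here. The submitters' processing notes name bcl2fastq version 1.8.4, Subread version 1.5.0, featureCounts and genome build mm10, without giving the role of each. The annotation behind the counting, the handling of reads that map to several places and the filters are not given in the sources used here.

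The deposited values are whole-number counts per gene, not normalised, with 1 column per embryo. The deposited count matrix has 27179 genes under numeric gene identifiers, and the 8 separate per-embryo count lists were identical to its columns. Gene symbols, biotypes and positions came from an NCBI RefSeq table of assembly GRCm38.p6, the assembly on which mm10 is based, matched on the numeric identifier. A symbol was found for 25275 identifiers and not for 1904. Identifiers without a symbol stayed in the library totals and in the test, and held between 0.490% and 1.639% of the counts of a library. Coordinates are 1-based. No columns of per-sample values were left unused.

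Each library held 39590959 to 44788200 counts, so that 3 counts, the upper limit that a count of 0 allows, correspond to 0.0670 to 0.0758 CPM of the library total (counts scaled to the library size). Such limits cover counting error only, because reads without molecular identifiers are not independent molecules. No pair of libraries within a group agreed within sampling noise: the chi-square per gene between pairs was 4.22 to 14.6 over genes with at least 20 counts in the pair.

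Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 16074 genes. Library sizes were scaled with TMM factors, which lay between 0.971 and 1.028. Groups were compared with edgeR's quasi-likelihood test with robust estimation, without covariates, over all 8 libraries. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are Taf8-deleted minus Taf8-intact. Their standard error (SE) was derived from the fold change and the F statistic of the test. Unless library totals are named, CPM values use the TMM-scaled library sizes and are given as mean ± SD over 4 libraries. Because the libraries are unstranded, reads of overlapping genes on opposite strands cannot be told apart, and members of near-identical families such as histones, ribosomal proteins and haemoglobins can share reads.

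A total of 34 gene lists, covering transcription complexes, pathways and markers of cell types that a dissected cortex could hold, were fixed before the data were examined, as were the tests between the groups, the alternatives other than those named below as added, and the rule for naming genes. The tests of possible explanations were set later, several of them after the results were seen. Each list was tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 34 lists. Camera compares a list with all other genes. It was repeated with a correlation estimated for each list. Fry was run beside it: its directional p tests whether the genes of a list move, on balance, one way, its mixed p whether they change in either direction, and neither compares the list with other genes. List members were counted over all genes tested and again adjusted over the list alone. A list of sex chromosome genes served only as a check. Genes near Taf8 were compared with the rest by Fisher's exact test, two-sided.

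The text names Taf8, the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups, up to 4 members of each list with the smallest p together with members needed to show the opposite direction, and up to 3 genes near Taf8. Gene models without an established name, pseudogenes, sex chromosome genes of the check list and identifiers without a symbol were left out of the largest rises and falls. Genes named outside this rule are said to be so, and values of some genes that the rule takes are not reported here.

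Some alternatives left out 2 libraries or the identifiers without a symbol and were chosen after seeing the data. The alternatives chosen beforehand were other size factors (median ratio, upper quartile, library totals only), no filter or a filter at a CPM above 1 in 4 libraries, DESeq2 1.42.0, limma voom without and with quality weights, edgeR's test against a 1.5-fold change, the replicate number as a block, a correction for gene length and GC content by splines, and leaving out each library. GC content was known for 90.9% of the genes tested. The procedure was tested on simulated counts drawn from the means of the intact libraries and the library sizes of this comparison, with 15706 genes tested. Recovered were 61.2% of genes changed 1.25-fold, 81.6% of those changed 1.5-fold, 81.6% of those changed 2-fold and 98.0% of those changed 4-fold. Of 15509 unchanged genes 14 were called. Only 49 or 50 genes were changed at each fold, so the simulation does not cover data in which most genes change. Other calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.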

Results

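The data are gene counts from unstranded RNA sequencing of the cerebral cortex of 8 mouse embryos, 4 Taf8-intact and 4 Taf8-deleted. Taf8 encodes a subunit of TFIID, the general transcription factor that recognises core promoters and places RNA polymerase II at them. The comparison asks which transcripts differ in the embryonic cortex when Taf8 is lost. Total counts were 43931678, 43450597, 42320662 and 42715614 in the Taf8-intact libraries and 44788200, 42870312, 43179448 and 39590959 in the Taf8-deleted libraries. Y-linked Ddx3y was present in all 8 libraries with 1986 to 2385 counts, while Xist, the RNA of the inactive X chromosome, had 3 to 31 counts. The animal numbers were 408.4, 408.5, 408.6 and 409.2 for the intact embryos and 456.1, 472.1, 477.1 and 486.1 for the deleted embryos. Most intact embryos thus shared the number before the point, while each deleted embryo had its own. No number before the point occurred in both groups, the labels do not say what it marks, and the genotype cannot be separated from whatever it stands for. Whether the intact embryos are as independent of each other as the deleted ones is therefore not known.

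Taf8 mRNA was nearly absent from the Taf8-deleted cortex. Taf8 (gene ID 63856, chromosome 17, 47483364 to 47502321 in GRCm38) had 1491, 1383, 1222 and 1403 counts in the intact libraries and 30, 14, 29 and 14 in the deleted ones. This is 32.6 ± 2.07 CPM against 0.495 ± 0.187 CPM (SD, n = 4 each). It fell by 6.02 ± 0.15 (SE) on the log2 scale, with adjusted p = 2.42e-10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Every library therefore had the Taf8 level of its label. The counts cover the whole gene, and which exons the remaining reads came from was not analysed here.

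**Figure D1:**
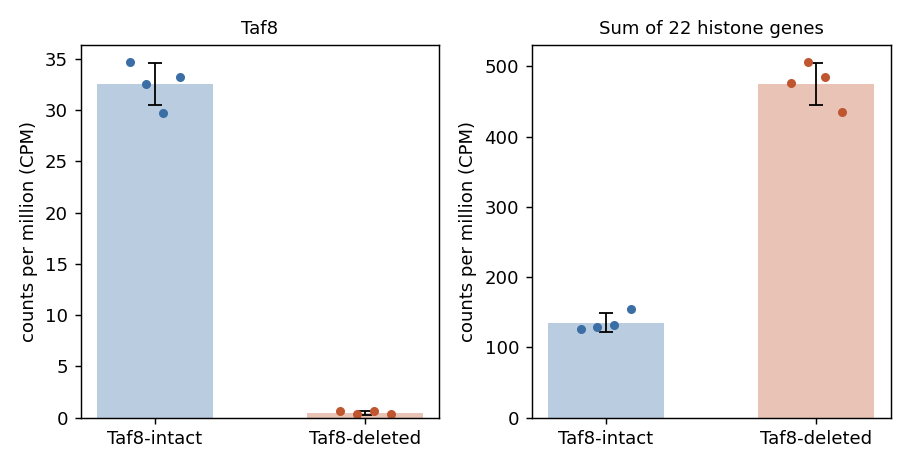
CPM of Taf8 (left) and summed CPM of 22 replication-dependent histone genes (right) in the 4 Taf8-intact and 4 Taf8-deleted libraries; points are libraries, bars the means and error bars the SD. Taf8 lies between 29.7 and 34.7 CPM in the intact and between 0.318 and 0.657 CPM in the deleted libraries, and the histone sum between 125.58 and 155.0 CPM in the intact and between 434.6 and 505.48 CPM in the deleted libraries.

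Loss of Taf8 was accompanied by changes in most of the expressed genes, most of them small. Of 16074 genes tested, 4919 rose and 5290 fell in Taf8-deleted cortex by edgeR's quasi-likelihood test, 63.5% of the total. This balance depends on the scaling, since TMM centres the changes near 0: 5894 genes were higher and 4416 lower with library totals only, and 5837 and 4480 with upper-quartile factors. Under TMM, 1773 of the rises and 1534 of the falls reached 1.5-fold, and 863 and 486 reached 2-fold. The median absolute log2 fold change of the called genes was 0.398, and the biological coefficient of variation between embryos was 7.57%. The values of the 4 deleted and the 4 intact libraries did not overlap for 9279 genes, or 57.7%, where chance gives 2.86%. Over the 500 most variable genes the first principal component held 69% of the variance and separated the groups, from -24.59 to -18.54 in the intact and from 15.07 to 28.33 in the deleted libraries. Tested against a 1.5-fold change in place of any change, 932 genes were higher and 816 lower.

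Under the rule for named genes, the largest rises were in 5 histone genes, a chemokine gene and genes of a homeobox and a zinc finger protein. The linker histone gene H1f2 rose from 10.7 ± 2.10 to 73.6 ± 3.67 CPM (SD, n = 4 each). The core histone genes H2ac6, H2bc6, H4c9 and H2bc4 rose by 3.99, 3.94, 3.85 and 3.34 on the log2 scale, with SE of 0.09 to 0.13. Dbx1, a homeobox gene known from ventral progenitor domains, rose from 1.27 ± 0.374 to 14.8 ± 0.806 CPM, and Zbtb42, a zinc finger gene, from 2.46 ± 0.217 to 12.9 ± 1.34 CPM. The largest rise was that of Ccl27a, a chemokine gene, from 0.308 ± 0.0779 to 12.2 ± 4.18 CPM. Ccl27a overlaps Il11ra1 on chromosome 4, H2bc6 overlaps a gene model, and histone genes share near-identical sequence, so the reads of these genes cannot be assigned with certainty.

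After Taf8, the largest falls were in the enzyme genes Aldh1a3, Scd1 and Dct, the G protein-coupled receptor genes Gipr, Mc4r and Sstr3, and the repressor gene Bcl6. Aldh1a3, encoding a retinaldehyde dehydrogenase that makes retinoic acid, fell from 7.64 ± 0.328 to 0.858 ± 0.151 CPM (SD, n = 4 each). Scd1, the stearoyl-CoA desaturase, fell from 31.6 ± 4.12 to 4.31 ± 0.265 CPM. The receptor genes Gipr, Mc4r and Sstr3, for the incretin GIP, melanocortins and somatostatin, had log2 fold changes of -2.98 ± 0.13, -2.53 ± 0.20 and -2.45 ± 0.10 (SE). Bcl6, a repressor that promotes neurogenesis, fell from 10.4 ± 1.34 to 1.67 ± 0.319 CPM. Dct, encoding dopachrome tautomerase, fell from 14.6 ± 0.575 to 2.54 ± 0.856 CPM. Bcl6 overlaps a gene model. All of these genes had adjusted p of at most 1.64e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

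**Figure D2:**
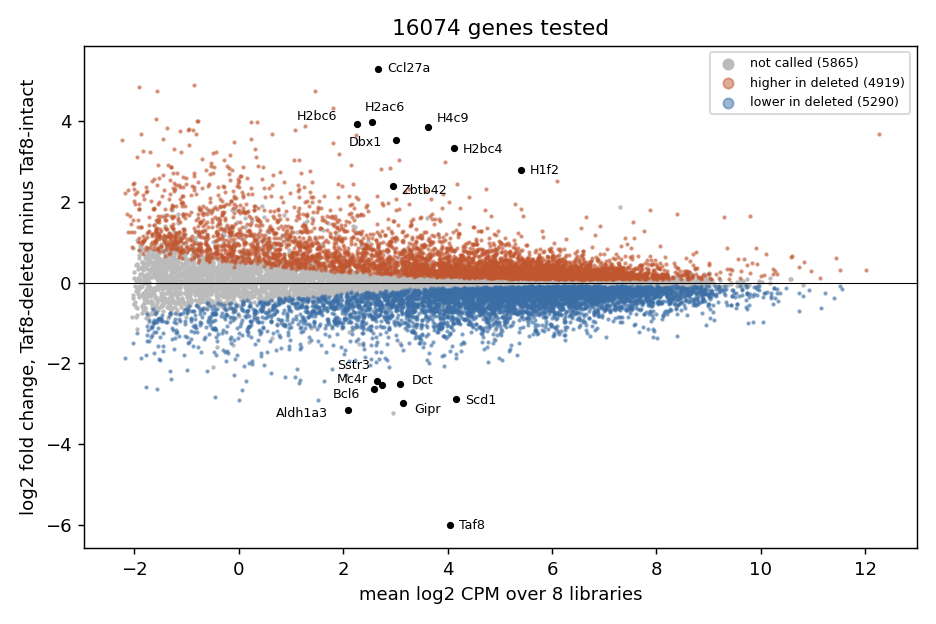
Log2 fold change (Taf8-deleted minus Taf8-intact) against mean log2 CPM over the 8 libraries for the 16074 genes tested; orange and blue points are the 4919 genes that rose and the 5290 that fell, grey points the 5865 that were not called, and black points Taf8 and the genes with the largest rises and falls. Taf8 lies at -6.02 and Ccl27a at 5.30.

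Of the 34 gene lists, 14 were called by camera with the preset correlation, 7 upward and 7 downward. None was called with a correlation estimated for each list, where the lowest adjusted p was 0.219. This loss does not rest on correlation alone, since camera then also uses only the 6 residual degrees of freedom. Ribosomal protein genes had an estimated correlation of 0.012, near the preset value, yet went from a camera adjusted p = 0.0070 to 0.261. Upper-layer markers had a correlation of -0.012 and went from 0.0038 to 0.219. Fry found 24 lists moving on balance one way and 32 changing in either direction. The counts below are by edgeR's quasi-likelihood test over all genes tested, and the count adjusted over the list alone was the same unless it is given.

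Most other TFIID subunits and several general transcription factors rose. Of 13 TFIID subunits other than Taf8, 10 rose and 1 fell, and the counts adjusted over the list alone were 10 and 1 (camera adjusted p = 0.0012; adjusted p = 0.261 with an estimated correlation). Taf13 rose by 1.09 ± 0.06, Taf12 by 0.86 ± 0.04, Taf5 by 0.74 ± 0.04 and Taf6 by 0.46 ± 0.03 (log2 ± SE). Taf7 went the other way and fell by 0.32 ± 0.06. Of 17 subunits of the other general transcription factors, 11 rose and none fell (camera adjusted p = 0.0079; adjusted p = 0.406 with an estimated correlation), led by the TFIIA gene Gtf2a1 at 1.41 ± 0.05, the TFIIB gene Gtf2b at 0.58 ± 0.04 and the TFIIH helicase gene Ercc3 at 0.52 ± 0.04. Among 12 RNA polymerase II subunits, 7 rose and 2 fell, and the list was not called (camera adjusted p = 0.212). The gene of the largest subunit, Polr2a, rose from 430 ± 18.9 to 1345 ± 60.5 CPM (SD, n = 4 each), while Polr2b rose by 0.32 ± 0.04 and Polr2i fell by 0.45 ± 0.06. Of 16 subunits of SAGA, a coactivator complex that shares TAF proteins with TFIID, 5 rose and 8 fell (camera adjusted p = 0.171). Tada1, Kat2b, Supt7l and Atxn7l3 fell by 0.75, 0.60, 0.52 and 0.44 with SE of 0.04 to 0.06. Taf5, Taf6, Taf7, Gtf2a1, Gtf2b, Polr2b, Polr2i, Tada1, Kat2b and Atxn7l3 overlap other annotated genes, whose reads cannot be told apart from theirs without strand.

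Replication-dependent histone mRNAs rose together, while mRNAs of ribosomal proteins and of cholesterol synthesis fell. Of 22 histone genes, 20 rose and none fell, with a median log2 fold change of 2.79 (camera adjusted p = 1.87e-08; adjusted p = 0.219 with an estimated correlation). H1f4, a linker histone gene, rose by 3.46 ± 0.15 (SE). Because near-identical histone genes can share reads, their sum was also taken. It was 135 ± 13.5 CPM in intact and 475 ± 29.8 CPM in deleted cortex (SD, n = 4 each). These reads come from libraries of polyadenylated RNA and do not show whether all histone mRNA rose. Of 20 genes of the cholesterol pathway, 18 fell and none rose (camera adjusted p = 4.10e-06; adjusted p = 0.327 with an estimated correlation). Fdps, Fdft1, Msmo1 and Sqle, which encode enzymes of the pathway, fell by 1.11, 0.97, 0.81 and 0.67 with SE of 0.04 to 0.07. Of 28 ribosomal protein genes, 18 fell and 5 rose (camera adjusted p = 0.0070; adjusted p = 0.261 with an estimated correlation). Rpl4 fell by 1.06 ± 0.04, Rpl7 by 0.70 ± 0.03 and Rpl8 by 0.52 ± 0.04. Rpl11 went the other way and rose from 1.64 ± 0.120 to 5.10 ± 0.611 CPM. Ribosomal protein genes have many processed pseudogenes, and Rpl4, Fdps and Fdft1 overlap other annotated genes, so single values are uncertain.

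Immediate early and interferon-stimulated genes rose, and the p53 target list was not called. Of 9 immediate early genes, which respond within minutes to stimuli, 7 rose and none fell (camera adjusted p = 0.0026; adjusted p = 0.406 with an estimated correlation). Egr1 rose by 1.71 ± 0.10, Ier2 by 1.03 ± 0.08, Arc by 1.01 ± 0.08 and Jun by 0.47 ± 0.05 (log2 ± SE). Of 13 interferon-stimulated genes, 12 rose and none fell (camera adjusted p = 0.0026; adjusted p = 0.627 with an estimated correlation). The mean log2 CPM of this list was 1.21, 1.08, 1.38 and 0.51 in the deleted and -0.26, -0.14, -0.46 and 0.24 in the intact libraries, and that of the meningeal markers was 2.73, 3.19, 3.27 and 0.92 in the deleted and 1.22, 1.01, 0.77 and 1.96 in the intact libraries. In both lists replicate 4 was the lowest of the deleted and the highest of the intact libraries. Isg15 rose from 1.12 ± 0.206 to 4.54 ± 0.684 CPM and Usp18 from 0.125 ± 0.0760 to 1.18 ± 0.483 CPM (SD, n = 4 each). Of 31 p53 target genes, 6 rose and 6 fell (camera adjusted p = 0.911). Btg2 and Ddb2 rose by 0.52 ± 0.05 and 0.67 ± 0.09, and Sesn1 and the proapoptotic gene Bbc3 fell by 0.42 ± 0.03 and 0.58 ± 0.09. Of 21 genes of the ATF4 stress response, 6 rose and 8 fell (camera adjusted p = 0.664), among them the amino acid transporter gene Slc7a5 at 0.63 ± 0.07 and Pck2 at -0.59 ± 0.07. Their median was -0.09 and their mean 0.01. Of 16 genes of the apoptosis machinery, 4 rose and 8 fell (camera adjusted p = 0.765). Bcl2l11 and Diablo, both proapoptotic, rose by 0.52 ± 0.04 and 0.42 ± 0.03, and Bid, also proapoptotic, and Bcl2, which is antiapoptotic, fell by 0.68 ± 0.09 and 0.43 ± 0.06. Of 17 hypoxia and glycolysis genes, 4 rose and 9 fell (camera adjusted p = 0.350), including the glucose transporter gene Slc2a3 at -0.57 ± 0.06. Isg15, Usp18, Ddb2, Bcl2l11, Diablo, Bid, Bcl2 and Slc2a3 overlap other annotated genes.

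**Figure D3:**
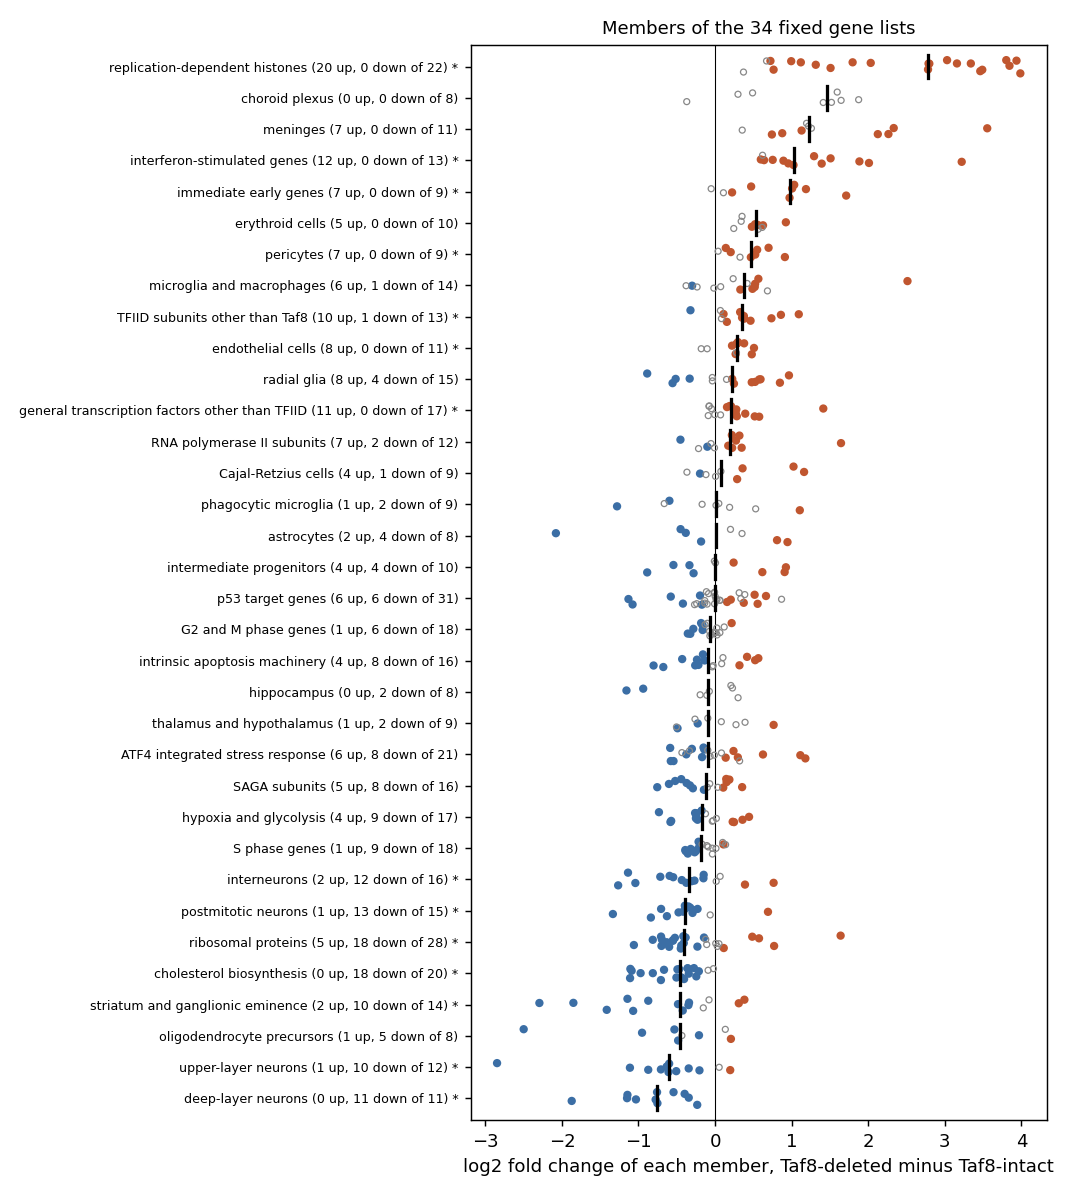
Log2 fold change (Taf8-deleted minus Taf8-intact) of every tested member of the 34 gene lists, with a black bar at each list's median; filled orange and blue points rose or fell by edgeR's quasi-likelihood test, open points did not pass, and an asterisk marks the 14 lists called by camera with the preset correlation, none of which was called with an estimated correlation. Histone genes lie highest at a median of 2.79 and deep-layer neuron markers lowest at -0.76.

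Radial glial genes changed in both directions, and the cell cycle genes that changed mostly fell. Of 15 radial glia markers, 8 rose and 4 fell, and 9 and 4 passed when adjusted over the list alone (camera adjusted p = 0.322). Nes rose from 682 ± 62.1 to 1228 ± 38.6 CPM (SD, n = 4 each), Vim by 0.59 ± 0.05 and Sox9 by 0.58 ± 0.06 (log2 ± SE), while Fabp7 fell by 0.51 ± 0.06. Of 10 intermediate progenitor markers, 4 rose and 4 fell (camera adjusted p = 0.911), with a median of -0.001 and a mean of 0.065. The Notch ligand genes Dll1 and Dll3 rose by 0.91 ± 0.06 and 0.93 ± 0.07, and Gadd45g by 0.62 ± 0.05, while the somatostatin receptor gene Sstr2 fell by 0.89 ± 0.08. Of 18 S phase genes, 9 fell and 1 rose (camera adjusted p = 0.143), among them Uhrf1 at -0.39 ± 0.06 and the replicative helicase gene Mcm7 at -0.32 ± 0.04. Of 18 G2 and M phase genes, 6 fell and 1 rose, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.445), among them Cdk1 at -0.36 ± 0.06 and Ccnb2 at -0.32 ± 0.06. Without intact replicate 3 the S phase list was called lower (camera adjusted p = 0.0083; adjusted p = 0.0387 with voom quality weights over all libraries), as was the G2 and M phase list (camera adjusted p = 0.0482). Over all libraries both had an adjusted p = 0.893 with an estimated correlation. Mcm7 and Sstr2 overlap other annotated genes.

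Markers of cortical neurons fell, with a median log2 fold change of -0.76 for deep-layer, -0.60 for upper-layer and -0.39 for general neuronal markers. All 11 deep-layer markers fell (camera adjusted p = 1.29e-04; adjusted p = 0.261 with an estimated correlation). Sox5, which controls deep-layer fate, fell from 336 ± 23.5 to 151 ± 9.72 CPM (SD, n = 4 each), Bcl11b by 0.76 ± 0.04, Fezf2 by 0.75 ± 0.05 and Foxp2 by 0.54 ± 0.04 (log2 ± SE). Of 12 upper-layer markers, 10 fell and 1 rose (camera adjusted p = 0.0038; adjusted p = 0.219 with an estimated correlation). Cux1 fell by 0.63 ± 0.04, Pou3f2 by 0.71 ± 0.05 and Unc5d by 0.87 ± 0.08. Of 15 general markers of postmitotic neurons, 13 fell and 1 rose (camera adjusted p = 0.0026; adjusted p = 0.627 with an estimated correlation). The neurogenic factor genes Neurod6 and Neurod2 fell by 1.33 ± 0.06 and 0.84 ± 0.04 and the synapsin gene Syn1 by 0.63 ± 0.04, whereas the neurofilament gene Nefm rose by 0.69 ± 0.05. Of 16 interneuron markers, 12 fell and 2 rose (camera adjusted p = 0.0390; adjusted p = 0.618 with an estimated correlation). Gad2, a GABA-synthesising enzyme gene, fell by 1.14 ± 0.05, Lhx6 by 1.04 ± 0.06 and Npy by 1.26 ± 0.13, while Dlx6, which overlaps antisense genes, rose by 0.77 ± 0.07. The camera call of the interneuron list was lost without intact replicate 1 (adjusted p = 0.0585) and without deleted replicate 4 (adjusted p = 0.0544), and with the filter at a CPM above 1 in 4 libraries (adjusted p = 0.0507). Of 9 markers of Cajal-Retzius cells, the early neurons of the cortical surface, 4 rose and 1 fell (camera adjusted p = 0.491), led by Ebf3 at 1.16 ± 0.08 and Ebf2 at 1.02 ± 0.12. Sox5, Foxp2, Cux1, Unc5d, Syn1, Nefm, Gad2, Ebf3 and Ebf2 overlap other annotated genes.

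Endothelial and pericyte markers rose, and glial markers changed in both directions. Of 8 markers of oligodendrocyte precursors, 5 fell and 1 rose (camera adjusted p = 0.258), with Gpr17 falling from 3.74 ± 1.08 to 0.656 ± 0.232 CPM (SD, n = 4 each) and Olig1 by 0.53 ± 0.11 (log2 ± SE). Of 8 astrocyte markers, 2 rose and 4 fell (camera adjusted p = 0.769), with a median of 0.01 and a mean of -0.10. Aldh1l1, an astrocyte folate enzyme gene, fell from 24.8 ± 1.86 to 5.87 ± 0.637 CPM, and Id3 rose by 0.81 ± 0.14. Of 11 endothelial markers, 8 rose and none fell (camera adjusted p = 0.0332; adjusted p = 0.652 with an estimated correlation), including the tight junction gene Cldn5 at 0.51 ± 0.08 and Cdh5 at 0.48 ± 0.08. Of 9 pericyte markers, 7 rose and none fell (camera adjusted p = 0.0328; adjusted p = 0.627 with an estimated correlation), including Rgs5 at 0.55 ± 0.06 and Abcc9 at 0.53 ± 0.05. The endothelial call was lost without intact replicate 1 (adjusted p = 0.0763) and without deleted replicate 1 (adjusted p = 0.0575), and the pericyte call without deleted replicate 3 (adjusted p = 0.0533); with library totals only both were lost (adjusted p = 0.0543). Without deleted replicates 2 and 3, an alternative chosen after seeing the data, the median of the pericyte markers went from 0.468 to 0.145 and the call was lost (adjusted p = 0.0647), and without intact replicate 4 and deleted replicate 1 the endothelial call was lost (adjusted p = 0.0690). The collagen mRNA Col3a1, chosen after its values were seen, was at 17.2, 49.6, 62.2 and 8.25 CPM in the deleted and at 6.97, 5.99, 6.30 and 12.2 CPM in the intact libraries. Of 14 microglia and macrophage markers, 6 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.233); C1qc rose by 0.57 ± 0.11 and Cx3cr1 fell by 0.30 ± 0.07. Of 9 markers of phagocytic microglia, 1 rose and 2 fell (camera adjusted p = 0.911): Lyz2 rose by 1.11 ± 0.21, and Lpl and Cd63 fell by 1.28 ± 0.12 and 0.60 ± 0.09. Their median was 0.01 and their mean -0.09. Gpr17, Aldh1l1, Cdh5, Abcc9 and Cx3cr1 overlap other annotated genes.

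Markers of striatum and ganglionic eminence fell, and 7 of 11 meningeal markers rose. Of 14 markers of striatum and ganglionic eminence, 10 fell and 2 rose (camera adjusted p = 0.0055; adjusted p = 0.261 with an estimated correlation). The dopamine receptor gene Drd1 fell from 6.84 ± 1.37 to 1.39 ± 0.193 CPM (SD, n = 4 each), Ikzf1 by 1.85 ± 0.12, Rxrg by 1.41 ± 0.08 and Lhx8 by 0.87 ± 0.06 (log2 ± SE). Of 8 hippocampal markers, 2 fell and none rose (camera adjusted p = 0.396): Zbtb18, which cortical neurons also express, by 0.94 ± 0.05 and Zbtb20 by 1.16 ± 0.16. Of 9 markers of thalamus and hypothalamus, 1 rose and 2 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.911, direction up, with a median of -0.09 and a mean of -0.01); Barhl2 rose by 0.77 ± 0.10. Of 11 meningeal markers, 7 rose and none fell (camera adjusted p = 0.0664). Crabp2 rose by 0.88 ± 0.13 and Foxc1 by 0.74 ± 0.17, and the list was called higher without intact replicate 4 (camera adjusted p = 0.0357) or without deleted replicate 4 (camera adjusted p = 0.0035). It was also called with no filter on low counts (adjusted p = 0.0347), with voom quality weights (adjusted p = 0.0313), and with the length and GC correction without (adjusted p = 0.0441) or with the replicate block (adjusted p = 0.0313). Over all libraries it had an adjusted p = 0.786 with an estimated correlation. The collagen mRNA Col1a2 was at 13.8, 25.4, 34.8 and 4.84 CPM in the deleted and at 3.56, 2.99, 2.87 and 7.02 CPM in the intact libraries. None of 8 choroid plexus markers passed the test (camera adjusted p = 0.572), and Ttr, the transthyretin mRNA of that tissue, chosen after its values were seen, ranged from 0.549 to 822 CPM among the deleted and from 1.51 to 257 CPM among the intact libraries. Of 10 erythroid markers, 5 rose over all genes tested and none adjusted over the list alone (camera adjusted p = 0.0957). That list was called higher without deleted replicate 4 (camera adjusted p = 0.0107), with the replicate block (adjusted p = 0.0426) and with voom quality weights (adjusted p = 0.0387). Over all libraries it had an adjusted p = 0.652 with an estimated correlation. Ikzf1 and Zbtb20 overlap other annotated genes.

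**Figure D4:**
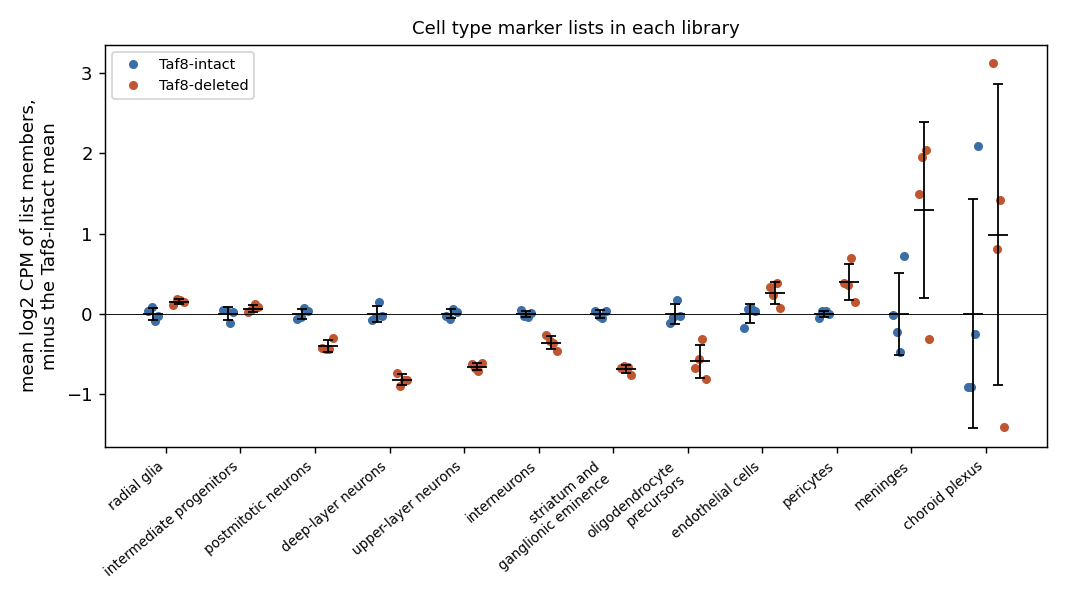
Mean log2 CPM of the members of 12 cell type marker lists in each library, shown relative to the mean of the 4 Taf8-intact libraries; points are libraries, and horizontal marks and error bars the mean and SD of each group of 4. Deep-layer markers were lower by -0.82 on average in the deleted libraries, whereas meningeal and choroid plexus markers had SDs of 1.10 and 1.88 log2 units among the deleted libraries.

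No difference was found between the share of called genes near Taf8 on chromosome 17 and elsewhere. Within 5 Mb of Taf8, 60 of 94 genes were called, or 63.8%, against 63.8% of 15528 genes elsewhere, with an odds ratio of 1.00 (95% confidence interval 0.647 to 1.58; Fisher's exact test, two-sided, p = 1.0000). The gene with the smallest p there was Aars2 (45503515 to 45520843), encoding the mitochondrial alanyl-tRNA synthetase, which fell from 28.2 ± 1.11 to 7.76 ± 0.476 CPM (SD, n = 4 each). Abcc10, a transporter gene that overlaps Dlk2, and Dnph1, a nucleotide hydrolase gene, each rose by 0.99, with SE of 0.05 and 0.06.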

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

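The tests on histone mRNAs and on neuronal markers were chosen after the results were seen, whereas those on lncRNA genes and on other splits of the libraries were set before their outcome was seen; the scaling of the summed CPM values to TMM library sizes was chosen after values on library totals were seen.

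Only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, called as many as 10209 genes. The highest of the other splits called 1. Every other split mixes the genotypes within its groups, which lowers its count, so this does not measure how far chance is excluded. Chance cannot be excluded for the number of gene lists called by camera with the preset correlation: 9 of the 35 splits gave as many as the 14 of the real one, and the highest of the others called 18. The other splits that reached 14 all exchanged 1 library between the groups, which leaves part of the genotype difference in place. The 18 splits that exchanged 2 libraries called at most 11 lists.

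Histone mRNAs rose in the deleted cortex by 2.23 ± 0.072 (log2 ± SE) on average over the list. More cells in S phase could raise them, but the S phase list did not rise and changed by -0.148 ± 0.063. The test asked for a rise of at least 0.558, a bound set by choice as a share of the histone rise. The libraries hold polyadenylated RNA, and how their histone reads scale with the number of cells in S phase was not measured. The comparison therefore cannot decide whether more cells in S phase contributed. Reads moved between near-identical histone copies would leave the sum over the copies as it was. The summed CPM of the 69 replication-dependent histone genes counted, inside and outside the list, rose by 1.495 ± 0.069. Reads dropped at counting are not seen in this sum. The sum of the 47 genes outside the list rose by 0.828 ± 0.05, less than the 1.818 ± 0.083 of the list. Carry-over of RNA without poly(A) tails stays open. Outside the histones, 5 such RNAs were measured, with a median of 0.687 that lies below the lower quartile of the histone list (1.169). However, 2 of them rose, Rn7sk by 0.70 and Rnu7 by 1.438. An identifier of undetermined kind without a symbol, not among the 5, had 6241 to 11149 CPM of library totals in the deleted libraries. In the intact libraries it had 579 to 882. Like the sum of the histone list, it was highest in replicate 4 among the intact libraries. Among the deleted libraries both were highest in replicate 2 and lowest in replicate 4. Loss of Taf8 itself may change histone mRNA levels or their polyadenylation, which was not tested.

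Neuronal markers fell in the deleted cortex, the general ones by a mean of -0.401 ± 0.047 and the layer markers by -0.734 ± 0.044 (log2 ± SE). Dilution by tissue without neurons, if it acted alone, would lower both alike, and the difference between them was -0.333 ± 0.036 (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 can give). Such dilution combined with a further fall of the layer markers was not tested and stays open. Dilution by striatum or ganglionic eminence, if it acted alone, would raise their markers, which changed by -0.689 ± 0.035. Such dilution combined with a fall of these markers in the deleted embryos was not tested and stays open. A lower share of neurons with no other change would raise all other cell types alike. Markers of oligodendrocyte precursors, however, changed by -0.911 ± 0.061 relative to those of endothelial cells and pericytes (exact permutation test, two-sided, p = 0.0286). Dilution by other brain tissue that holds neurons was not excluded either, with changes of -0.264 ± 0.131 for hippocampal and 0.054 ± 0.194 for thalamic and hypothalamic markers. A lower share of neurons together with changes inside the remaining cells stays open too, and so does the genotype acting on neuronal gene expression.

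The lncRNA genes rose far more often than they fell, 396 against 83 of 762, with a median log2 fold change of 0.502. Their low abundance alone would give protein-coding genes of the same abundance the same median, but 10000 draws of such genes had a median of 0.101 and at most 0.199. Reads from DNA or unspecific transcription remain a possible explanation, since the summed CPM of sensory receptor, keratin-associated and defensin genes, which cortex is not known to use, rose by 0.714 ± 0.19 (SE; exact permutation test, two-sided, p = 0.0286). That value lies above the lncRNA median by less than 2 SE and rests on 162 to 453 counts per library, from 199 genes. Whether such reads come from transcription near other genes or from DNA cannot be decided from unstranded counts.

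In 30 of 374 groups of 4 libraries, 1 library lay apart from the other 3 by Dixon's ratio (its gap to the nearest of the others divided by the range, above its 95% critical value), where chance alone gives about 1 in 20, or 18.7. The groups are not independent, since they share the same 8 libraries and the list means hold genes that were also tested singly. The excess over 18.7 therefore does not measure how far chance is excluded. Deleted replicate 4 and intact replicate 3 each accounted for 8 of the 30. Intact replicate 3 was apart, with ratios of 0.862 for Atxn7l3, 0.843 for Mcm7, 0.84 for Cdk1, 0.888 for Sox9, 0.871 for Unc5d and 0.924 for Lhx8, and with 0.834 for the mean of intermediate progenitor markers. Deleted replicate 4 was apart for H4c9 (0.831), Arc (0.874), Lhx6 (0.877), Id3 (0.902) and Hba-a2 (0.846), and for the means of the lists of p53 targets (0.951), postmitotic neurons (0.89) and striatum and ganglionic eminence (0.862). In the deleted group, replicate 3 was highest for Ccl27a (0.876), Cx3cr1 (0.913) and the mean of hypoxia and glycolysis genes (0.93), replicate 2 lowest for Pgk1 (0.961), Cacna2d2 (0.834) and Zbtb20 (0.891), and replicate 1 lowest for Tyms (0.891) and highest for Lpl (0.892). In the intact group, replicate 2 was highest for Ccl27a (0.866), Egr1 (0.851) and Lef1 (0.863), and replicate 4 was highest for Arc (0.923) and for the choroid plexus gene Clic6 (0.842) and lowest for Abcc9 (0.875).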

How the results depend on the processing

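The results without identifiers that lack a symbol, and those without deleted replicates 2 and 3 (highest in meningeal collagen mRNA) or without intact replicate 4 and deleted replicate 1 (highest in choroid plexus mRNA), were chosen after seeing the data. Over the alternatives run, none of the 155 genes and 34 lists followed that was called changed sign. Tested against a 1.5-fold change, 932 genes were higher and 816 lower. With an estimated correlation, 0 lists were called. The log2 fold change of Taf8 stayed between -6.18 and -5.84 when any 1 library was left out, the genes higher numbered 4617 to 5024, the genes lower 4876 to 5103, and the lists called 12 to 16. Without identifiers that lack a symbol, 4950 genes were higher and 5021 lower. Without deleted replicates 2 and 3 the numbers were 4219 and 4666 and the pericyte list lost its call (adjusted p = 0.0647); without intact replicate 4 and deleted replicate 1 they were 4524 and 4611 and the endothelial list lost its call (adjusted p = 0.0690). With library totals only, which moved the median of all genes by 0.062, 57.2% of calls were higher against 48.2% with TMM. DESeq2 called 4972 genes higher and 5085 lower, 96.7% of the calls by edgeR among them. The correction for gene length and GC content gave 4644 and 5656, and 92 of all genes called without it had the opposite sign. Of the 155 genes followed over the alternatives, 3385 results stayed on their side of the threshold, 161 lost the call (79 of these in the test against a 1.5-fold change) and 12 gained it; of the 34 lists 712 stayed, 24 lost it (14 of these with the estimated correlation) and 12 gained it. With the preset correlation, adjusted p over the alternatives ranged from 0.0086 to 0.0763 for endothelial cells, 0.0085 to 0.0647 for pericytes, 0.0105 to 0.0585 for interneurons, 0.0035 to 0.2257 for meninges, 0.0107 to 0.2257 for erythroid cells, 0.0083 to 0.2962 for S phase and 0.0482 to 0.7206 for G2 and M phase genes. The calls of Hba-a2, Hbb-b1, Slc4a1, Col1a2, Lhx9 and Rora were lost without any of several single libraries, that of Alas2 without intact replicate 3 (adjusted p = 0.0501) and that of Ccnb1 without intact replicate 2 (adjusted p = 0.0521).

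The replicate numbers did not pair the libraries: deviations from the group means correlated by -0.229, 0.005, 0 and -0.455 between libraries of the same number. A fit with the number as a block gave 4605 genes higher and 5060 lower, with Taf8 at -6.03, and with the length and GC correction 4363 and 5417, with Taf8 at -6.11. The odds ratio near Taf8 was 0.940 within 2 Mb and 1.10 within 10 Mb. The alternative with Y-linked expression as a covariate was not run, because Y-linked expression hardly varied within the groups (ranges 0.074 and 0.202 log2). Between the groups it did not overlap, so it cannot be separated from the genotype. Its log2 CPM of library totals was 7.621 to 7.695 in the intact and 7.742 to 7.944 in the deleted libraries. Of the 5 sex chromosome genes of the check list that were tested, 2 rose and 1 fell. Depth limits genes at low levels most, such as Usp18 at 0.125 CPM in intact cortex.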

Other observations

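All gene groups and genes in this part were chosen after the results were seen, and the calls are by edgeR's quasi-likelihood test over all genes tested. Fisher's exact tests in this part were thus run on groups picked with the results known, and they count genes of a group as independent. Their p-values therefore do not measure how unlikely the pattern of a group is. Most called genes for potassium channels, ionotropic glutamate receptor subunits and GABA-A receptor subunits fell in Taf8-deleted cortex. Of 16 glutamate receptor subunit genes 14 fell and none rose (Fisher's exact test, two-sided, of higher against lower calls relative to all other called genes, adjusted p = 3.06e-04), including Gria3 from 44.0 to 16.3 CPM and Grik3 from 313 to 161 CPM. Of 15 GABA-A receptor subunit genes 10 fell and 1 rose (adjusted p = 0.0183), including Gabra3 at -0.78 on the log2 scale. Of 77 potassium channel genes 41 fell and 7 rose (adjusted p = 4.41e-06), including Kcna1 at -1.99 and Kcnj10, the glial inward rectifier, at -1.68. Many genes of these groups are expressed mainly in neurons, and the mean log2 CPM of neuronal markers also changed, by -0.401 for postmitotic neurons, -0.818 for deep-layer neurons and -0.358 for interneurons. Of 361 genes of the Zfp and Znf zinc finger series 185 fell and 51 rose (adjusted p = 8.10e-17), with Zfp2 at -1.29 and Zfp180 at -0.74, while Zfp33b rose by 3.87.

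Of 13 protein-coding genes of the mitochondrial genome 10 rose and none fell (Fisher's exact test, adjusted p = 0.0012), with CYTB going from 2210 to 3348 CPM and ND5 from 1185 to 1846 CPM. Among the 10, COX2, ATP8 and ATP6 were at only 6.26, 0.923 and 4.31 CPM in intact cortex. Their adjusted p in edgeR's quasi-likelihood test was 0.0350 to 0.0426. Of 17 mitochondrial aminoacyl-tRNA synthetase genes 8 rose and 5 fell (adjusted p = 0.462), and Sars2 fell by 1.92, Aars2 by 1.86 and Wars2 by 1.23 while Iars2 rose by 0.73. Of 77 mitochondrial ribosomal protein genes 30 rose and 32 fell (adjusted p = 1.0000). Of 33 Mediator subunit genes, which link activators to the polymerase, 13 rose and 9 fell (adjusted p = 0.462), with Med16 at -0.71. Hexim1, an inhibitor of the elongation factor P-TEFb, rose from 49.4 ± 1.69 to 151 ± 8.87 CPM (SD, n = 4 each), and Polr2a and Caprin2 rose by 1.65 and 1.94.

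An identifier without a symbol in the reference used had 579 to 882 CPM of library totals, without TMM scaling, in the intact and 6241 to 11149 CPM in the deleted libraries, 0.624% to 1.115% of their counts. Whether it stands for a gene, a repeat or a locus of RNA without poly(A) tails was not determined. Calls by the length of the gene's span were not tested as a difference: of 3906 genes with the shortest spans (up to 9.03 kb) 1396 rose and 1052 fell, and of 3906 with the longest (58.0 to 2390 kb) 863 rose and 1613 fell. Among lncRNA genes, 145 of 258 that overlap no annotated gene rose and 29 fell, and 251 of 504 that overlap another gene rose and 54 fell.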
